A study of Mus musculus with 3 samples.

How the data were processed

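RNA abundance was measured on 3 two-channel mouse microarrays. On each array, per the labels, total RNA of a mammary tumor grown from MMTV-PyMT carcinoma cells infected with a GATA-3 retrovirus was in channel 1 (Cy5), and RNA of a tumor grown from cells infected with the empty vector was in channel 2 (Cy3). All 3 arrays carried the dyes the same way round, so a dye effect of a probe and a difference between the tumors enter every ratio together. Whether the 3 arrays held RNA of separate animals, and whether they shared a control RNA, is not given in the sources used here; p-values therefore measure the spread between these 3 arrays only, which may be technical. The arrays are numbered 1 to 3 in accession order, as names only. Arrays 2 and 3 share a title prefix and array 1 has another.

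The values are the authors' deposited log ratios, 1 per probe row and array, taken here as log2. The scanner's channel intensities were not used here, so brightness, background and saturation of a probe are unknown. The scanner, the background correction, the normalization, the base of the log and the direction of the ratio are not given in the sources used here. The deposited columns had medians of -0.02, -0.07 and -0.07, so that the authors' values were already centred close to 0. Their SDs were 0.562, 0.722 and 0.550. A positive value was read as GATA-3 tumor over empty-vector tumor. This direction is likely but unproven: the labels place the GATA-3 tumor in channel 1 and describe it as compared to the control, and the Gata3 probe was positive on all 3 arrays. If the sign were the opposite, every higher and lower below would swap. If the base were not 2, ratios and folds would change in size but not in sign or test. The number of arrays limits the precision.

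Of 38976 probe rows, 22973 (58.9%) had 1 gene symbol in the platform annotation, 0 had several and 16003 had none. All 22973 symbols were those of the mouse RefSeq gene table. Each array was centred on its median, probes of 1 symbol were averaged per gene, and probes without a symbol were kept as rows of their own. Rows with a value on all 3 arrays were tested, and 1 missing value fell out. This left 31059 rows, of which 15056 were named genes (9918 with 1 probe, 5138 with 2 or more) and 16003 were unnamed probes. The mean log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (an intercept-only fit with eBayes), with Benjamini-Hochberg adjustment over all rows and a threshold of 0.05. This form of the test compares a row's mean with the spread between arrays. It takes no account of an effect of the probe that recurs on every array.

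Before the data were examined, 23 gene lists were fixed (13 of cell type and differentiation markers, 10 of pathways; 487 genes, of which 407 were measured). Each list with at least 5 measured genes was tested with limma's camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists; an estimated correlation, ranks and fry were alternatives. The genes to be named were also fixed by rule: Gata3; the 15 largest positive and the 15 largest negative mean ratios among named genes past the threshold with 1 sign on all 3 arrays; and up to 4 members of each list with the smallest p. A gene named outside this rule is said to be so. For many lists the text gives only some of the members fixed by the rule. Alternatives covered the centring, the scaling between arrays, the missing-value filter, a robust eBayes, each probe on its own, a plain one-sample test, a fold threshold, a looser threshold, the sign, rows of high spread, and each array left out in turn.

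The tests were tried on simulated data with the arrays' own spread over 31059 rows. With 200 rows changed by a log2 ratio of 1, 33.5% were recovered and 0 unchanged rows were called. With a change of 0.5, 0 were recovered. So few changed rows make the adjusted threshold strict, and these shares do not carry over to the real arrays. There 55.8% of rows passed, among them Car1 at a mean of 0.26 (limma, adjusted p = 0.0453). With no changed gene but a random effect of each row (SD 0.55) common to the arrays, 18819 rows were called. This SD was that of the observed row means, so a count near that of the real arrays was built in. Among rows with such an effect, camera called 1 of 100 unshifted lists of 20 genes at an unadjusted p under 0.05. It called 32 of 100 lists shifted by 0.25 and 91 of 100 shifted by 0.5.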

Results

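The data set addressed what forced expression of GATA-3, a zinc-finger transcription factor of the mammary luminal lineage, changes in MMTV-PyMT tumors, a mouse model in which a viral oncogene drives luminal-type mammary carcinoma. Cultured carcinoma cells were infected with a GATA-3 retrovirus or the empty vector and transplanted into cleared fat pads, and RNA was taken from the outgrowths after 6 weeks. There was 1 group, of 3 arrays, each giving the log2 ratio of a GATA-3 tumor to an empty-vector tumor for 31059 rows (15056 named genes and 16003 unnamed probes). The empty-vector tumor is thus the background of every value. Across rows, which are not independent replicates, Pearson's r was 0.77 between arrays 1 and 2, 0.78 between arrays 1 and 3, and 0.95 between arrays 2 and 3.

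Gata3 itself had a positive ratio on every array, that is, higher in the GATA-3 tumors as the direction was read. Because this sign was part of the basis for that reading, it is no separate evidence for it. The single Gata3 probe gave a mean log2 ratio of 0.80 ± 0.06 (SD, n = 3), a 1.74-fold difference, with 0.74, 0.86 and 0.79 on arrays 1, 2 and 3 (limma, adjusted p = 0.00307). The dyes were not swapped, so an effect of this probe is not separated from expression. Where the probe lies in the transcript is not known, so it is open whether it detects the retroviral message, the endogenous one or both. The value was not extreme on these arrays: 11.9% of all rows (3688 of 31059) had a ratio as high, and so did 335 of the 976 olfactory and vomeronasal receptor genes, which are known as genes of sensory neurons.

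Beyond Gata3, the largest positive ratios among named genes included Fabp4, the fatty acid binding protein of adipocytes, at 1.84 ± 0.15 (3.58-fold), Slc16a12, a monocarboxylate transporter family member, at 1.75 ± 0.14, the adaptor Cd2ap at 1.71 ± 0.31 and Tead1, a DNA-binding partner of YAP, at 1.65 ± 0.43 (all SD, n = 3). The other 11 of the 15 were Vmn1r228, Smim3, Ankrd7, Tanc1, St8sia6, Spata1, Vmn1r65, Slco6c1, Olfr165, Olfr849 and Lce1g, between 1.63 and 1.85, and 4 of the 15 were vomeronasal or olfactory receptors. The largest negative ratio was that of the ribosomal protein gene Rps23 (-1.90 ± 0.39), followed by Lgi4 (-1.76 ± 0.34), Rpl10 (-1.75 ± 0.48) and the metallothionein gene Mt4 (-1.75 ± 0.35). Of the 15 largest, 5 were ribosomal protein genes, the others being Rpl39 (-1.74 ± 0.30), Rps16 (-1.73 ± 0.39) and Rpl35 (-1.56 ± 0.34). Histone genes gave 4 more, H2bc21, H2ac19, H3c6 and H2bc15, from -1.71 to -1.56. The rest were Id3, an inhibitor of basic helix-loop-helix factors, at -1.65 ± 0.57, Spi1, the myeloid transcription factor PU.1, at -1.58 ± 0.42, the suprabasal keratin Krt1 at -1.52 ± 0.32, and Enox1 at -1.64 ± 0.26. Adjusted p (limma) ran from 0.00307 to 0.00557 over these 30 genes, each of which rested on 1 probe. Histone and ribosomal protein genes have close copies, so cross-hybridization between them is not excluded.

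**Figure D1:**
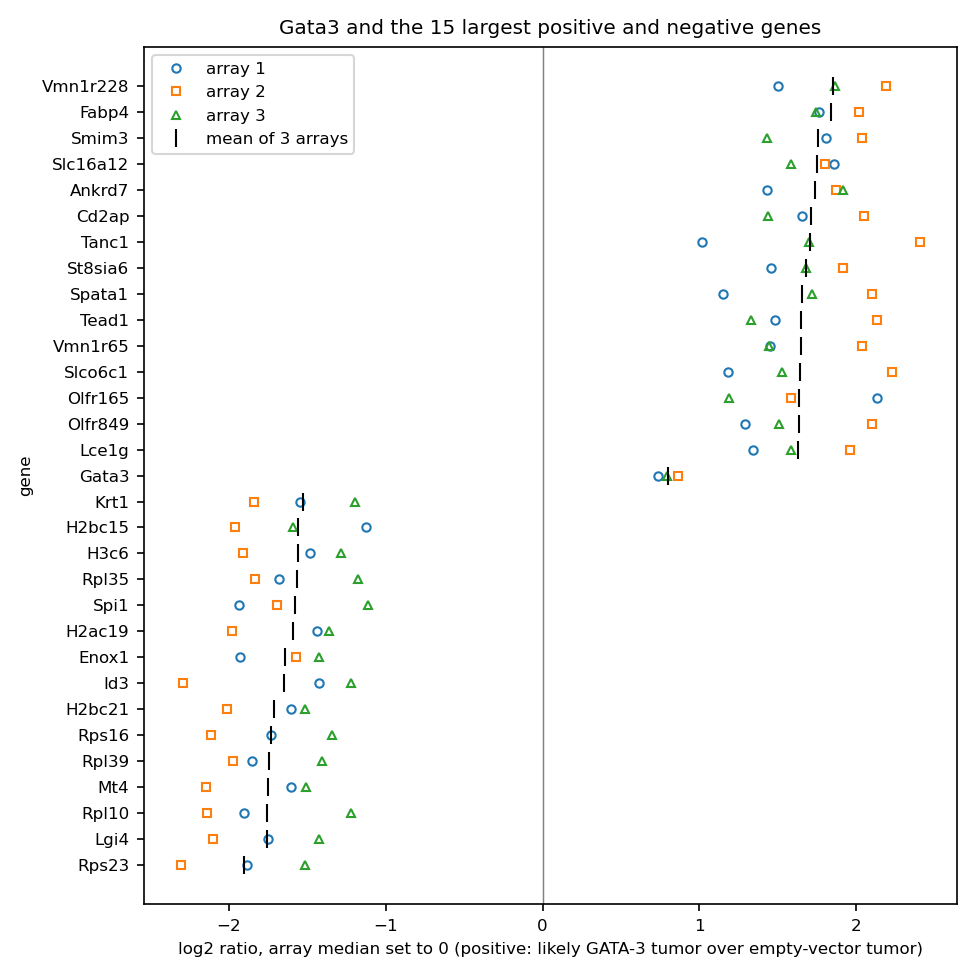
Log2 ratio of GATA-3 tumor over empty-vector tumor (x axis, array median set to 0, direction likely) on each of the 3 arrays for Gata3 and the 15 named genes with the largest positive and negative means (y axis); open symbols are arrays and the black tick is their mean. Gata3 lies at 0.80, under the lowest of the 15 largest positive means (1.63).

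In all, 17340 of 31059 rows (55.8%) passed the threshold, 9841 with a positive and 7499 with a negative ratio; among named genes these were 4836 and 3876. With a mean log2 ratio of at least 1 in size as well, 1572 were positive and 717 negative. The sign was the same on all 3 arrays for 76.4% of rows; the arrays share 1 dye orientation and may share control RNA, so no rate expected without change is given. Leaving out array 2 lowered the count to 11392 and leaving out array 3 to 8500. A plain one-sample test per row left 4 rows after adjustment, from 14156 at an unadjusted p under 0.05.

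Different probes of a gene did not move together to a like degree. Over the 3599 genes with exactly 2 probes, Pearson's r between the probes' mean ratios was 0.10 (Spearman's rho 0.11), a value across genes. Where both probes passed the threshold, 733 of 1307 pairs (56.1%; exact 95% binomial interval 53.3 to 58.8) had 1 sign, against 50.0% from the shares of positive and negative calls. Genes with many probes held both a wide range and, for most, a prevailing sign: of the 90 Lrp1 probes, the most of any gene, 79 were negative and the range was -1.36 to 1.37. In 13 of the 19 genes with 10 or more probes at least 75% of the probes had 1 sign, among them Ywhaz (71 of 77 positive) and Ctsd (all 15 negative), also named after their values were seen. Whether such probes differ in sequence is not known. Of 2 housekeeping genes named after their values were seen, the 32 Actb probes ran from -1.96 to 1.25 (23 positive), and the 30 Gapdh probes from -1.35 to 0.65 (26 negative). Of the 407 list genes described next, 270 rested on 1 probe.

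**Figure D2:**
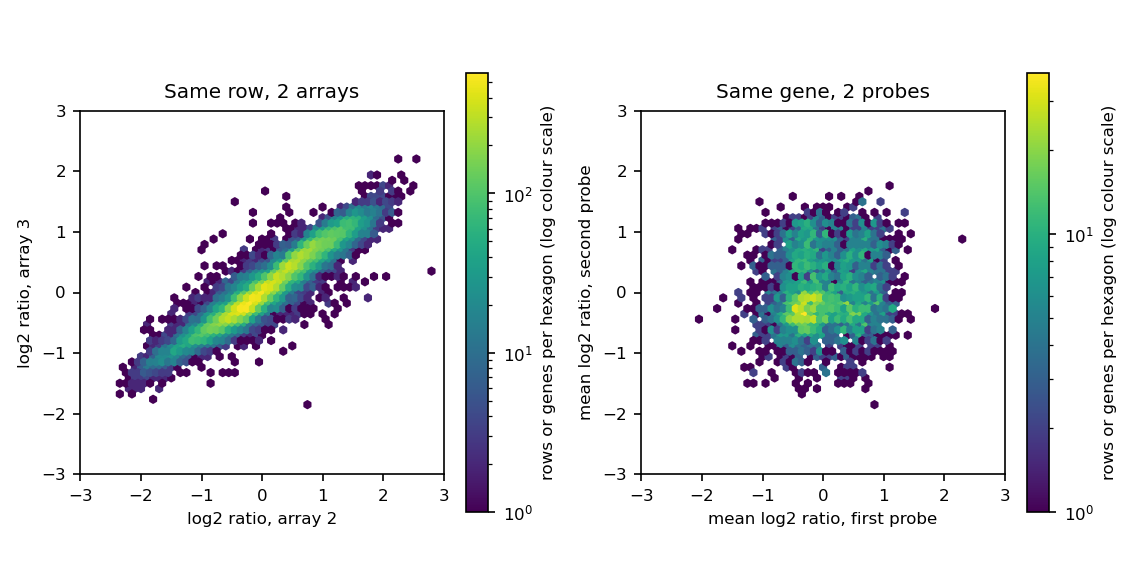
Left, log2 ratio of each of 31059 rows on array 2 (x axis) and array 3 (y axis); right, mean log2 ratio over 3 arrays of the 2 probes (x and y axes) of each of 3599 genes with exactly 2 probes; colour counts rows or genes per hexagon on a log scale. The arrays follow each other (r = 0.95) and the probes of a gene hardly do (r = 0.10).

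Luminal genes went both ways. For list genes, rose or up means a positive ratio past the threshold, and fell, down or lower a negative one. These words describe the ratio, in which an effect of the probe is not separated from expression. Of the 20 measured genes of the luminal and hormone response list, 5 rose, 7 fell and 8 did not pass. The luminal keratins Krt18 (-1.24 ± 0.20), Krt19 (-1.23 ± 0.37) and Krt8 (-0.90 ± 0.32; its 2 probes gave -1.25 and -0.56) were lower. The 5 that rose were Gata3, the pioneer factor Foxa1 (0.63 ± 0.35), Agr2, Myb and Prom1; the last 4, named after their values were seen, lost the call both without array 2 and without array 3 (Foxa1, adjusted p = 0.0577 and 0.0954). The 2 probes of Myb were of opposite sign (-0.25 and 1.04). The estrogen receptor gene Esr1, also named afterwards, gave 0.10 ± 0.31 (adjusted p = 0.539), with the sign turned to -0.06 without array 1. The list as a whole had a median of -0.03, and no shift was detected (camera, adjusted p = 0.848). Its median differed in sign between arrays, at -0.17, 0.025 and -0.05 on arrays 1, 2 and 3.

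Milk and alveolar genes held some of the largest ratios of any list. Of 18 measured, 8 rose and 4 fell. Casein alpha s1 (Csn1s1) reached 1.57 ± 0.24, although its 2 probes gave 0.85 and 2.30, and whey acidic protein (Wap) 1.39 ± 0.25, a 2.62-fold difference. Alpha-lactalbumin (Lalba), named after its value was seen, was at 0.65 ± 0.17. The beta- and kappa-casein genes, also named afterwards, did not pass: Csn2 gave 0.22 ± 0.18 (adjusted p = 0.119; 0.32 and adjusted p = 0.0238 without array 1) and Csn3 0.32 ± 0.33 (adjusted p = 0.113). The lipid droplet protein gene Plin2 (-1.10 ± 0.24) and the bile salt-stimulated lipase gene Cel (-0.75 ± 0.09) fell. The list median was 0.27 (camera, adjusted p = 0.848).

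Adhesion, basal and mesenchymal genes were likewise split. In the epithelial adhesion list 9 of 27 rose and 12 fell: E-cadherin (Cdh1) was at 0.80 ± 0.05 and desmocollin 2 (Dsc2) at 0.92 ± 0.14, while beta-1 integrin (Itgb1) was at -0.80 ± 0.05 with both probes negative, and plakophilin 3 (Pkp3) at -0.78 ± 0.10. In the basal and myoepithelial list 2 of 16 rose and 3 fell. Krt14 (0.69 ± 0.12) and Cnn1 (0.36 ± 0.06) rose. Sfn (-0.63 ± 0.22, both probes negative) and Myh11 (-0.35 ± 0.09) fell. So did Krt5, named after its value was seen, at -0.53 ± 0.37 (limma, adjusted p = 0.0345). In the mesenchymal transition list 6 of 20 rose and 8 fell. Foxc2 was at 1.11 ± 0.28 and Tcf4 at -0.78 ± 0.16. The paired regulators Twist2 (0.59 ± 0.06) and Twist1 (-0.59 ± 0.05) had opposite signs. In the invasion, protease and metastasis list 8 of 27 rose and 10 fell, with urokinase (Plau) at 0.73 ± 0.10, cathepsin L (Ctsl) at 0.95 ± 0.28 and the protease inhibitor Timp1 at -0.58 ± 0.11. No shift was detected in these 4 lists (camera, adjusted p = 0.848 each).

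In growth, stress and metabolic lists no shift was detected either. In the cell cycle list 12 of 36 rose and 8 fell; E2f1 (1.13 ± 0.21), cyclin A2 (Ccna2, 0.96 ± 0.16), cyclin E2 (Ccne2, 0.83 ± 0.11, both probes positive) and Mcm2 (0.80 ± 0.09) were its members of smallest p, 3 of them on 1 probe. Of those that fell, Cdk4 (-0.70 ± 0.12) and Birc5 (-0.59 ± 0.10), named after their values were seen, were negative on all 3 of their probes. Among cell cycle inhibitors and apoptosis genes 1 of 18 rose and 5 fell, and its members of smallest p, Cdkn1c, Cdkn2b, Bbc3 and Cdkn1a, at -0.57 to -0.37, lost the call without array 3 (adjusted p from 0.0580 to 0.104). All but Cdkn1c lost it without array 2 too, and the 2 probes of Cdkn1a were of opposite sign (-1.02 and 0.18). Immediate early and heat shock genes counted 5 up and 10 down of 24. Fosb (0.95 ± 0.05), Egr1 (0.99 ± 0.17) and Jund (1.01 ± 0.21) were up. The chaperone gene Hspa8 was at -1.38 ± 0.36, negative on all 3 of its probes. The interferon response list counted 6 and 6 of 21, with the RNA sensor Ifih1 at 1.17 ± 0.20 and Irf7 at -1.30 ± 0.32. Hypoxia and glycolysis genes counted 8 and 6 of 21, with Egln3 at 0.71 ± 0.06 and aldolase A (Aldoa) at -1.31 ± 0.33. Lipid and sterol synthesis counted 6 and 6 of 20, with Idi1 at 1.19 ± 0.36 and Hmgcs1, of the same pathway, at -1.25 ± 0.25. The T-cell GATA-3 program counted 2 and 3 of 10, with Ccr4 at 0.78 ± 0.05 and Crlf2 at -0.63 ± 0.11. Camera gave these 7 lists adjusted p from 0.848 to 0.926.

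Markers of other cell types that a tumor can hold were also measured. Adipocyte genes counted 5 up and 3 down of 15: Fabp4 led, resistin (Retn) was at 0.87 ± 0.14, Thrsp at -1.49 ± 0.12, and adiponectin (Adipoq), named after its value was seen, at -0.09 ± 0.13 (adjusted p = 0.437). Fibroblast and matrix genes counted 2 up and 8 down of 21, with collagen Col1a1 at -1.22 ± 0.29 and Mfap2 at -0.69 ± 0.20. Endothelial genes counted 5 and 5 of 15, with Plvap at -0.86 ± 0.07 and the receptor Tek at 0.81 ± 0.04. Kdr (1.05 ± 0.40) and Esam (0.46 ± 0.12) rose too. Macrophage and myeloid genes counted 4 and 5 of 21, with cathepsin S (Ctss) at 1.53 ± 0.14 and the integrin Itgam at -1.11 ± 0.32. Lymphocyte genes counted 4 and 4 of 15, with Cd3g at 0.77 ± 0.08 and Cd2 at -0.995 ± 0.16, both T-cell surface genes. Cd79a (0.63 ± 0.07) and Gzmb (0.87 ± 0.28) rose. Antigen presentation genes counted 4 and 3 of 12, with the class II chain H2-Aa at 1.57 ± 0.08 and the class I chain H2-K1 at 0.69 ± 0.04. Its 3 members that fell, named after their values were seen, were the class II invariant chain Cd74 (-0.68 ± 0.36), the class I chain H2-D1 (-0.33 ± 0.08) and B2m (-0.30 ± 0.15; 64 of 75 probes negative), and B2m lost the call whichever array was left out, H2-D1 without array 2 or array 3, and Cd74 without array 2. Skeletal muscle genes counted 2 and 6 of 13, with Eno3 at -1.52 ± 0.30, Casq1 at -1.51 ± 0.48 and Pvalb at 0.65 ± 0.16. Erythroid genes counted 4 and 0 of 6, with Alas2 at 0.58 ± 0.15; Hbb-b2 and Car1 lost the call whichever array was left out, and Epb42 without array 3. Epidermal genes counted 2 and 3 of 7, with loricrin (Lor) at 1.05 ± 0.10 beside Krt1, and Schwann cell genes 1 and 0 of 5, with Cldn19 at 0.65 ± 0.15.

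Over all 23 lists, limma's camera called 0 at the 0.05 threshold after adjustment, and 2 before it: skeletal muscle and fibroblast and matrix, both downward (adjusted p = 0.319 each). With an estimated correlation 0 were called, before or after adjustment (limma, adjusted p = 0.939 for every list). That form estimates the correlation from 3 arrays, with 2 residual degrees of freedom. Its power was not measured here, so its lack of calls is not read as absence of a shift. Fry called 0 lists in 1 direction, with 10 at an unadjusted p under 0.05, and all 23 for change in either direction. Fry compares list members with 0 and not with other rows. Since 55.8% of all rows passed the threshold, the 23 calls do not set these lists apart. The list genes passed the threshold about as often as all rows, 58.0% (236 of 407) against 55.8%. Adjusted over the list alone, the counts were those given, except for mesenchymal transition (7 up), interferon (7 down), hypoxia (8 down), basal (2 down), myeloid (4 down), lymphocyte (3 up, 2 down), antigen presentation (4 down) and muscle (7 down). The median and mean differed in sign for the mesenchymal, endothelial, myeloid, lymphocyte, antigen presentation and Schwann cell lists, and camera's direction was downward for lipid synthesis against a median of 0.05.

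**Figure D3:**
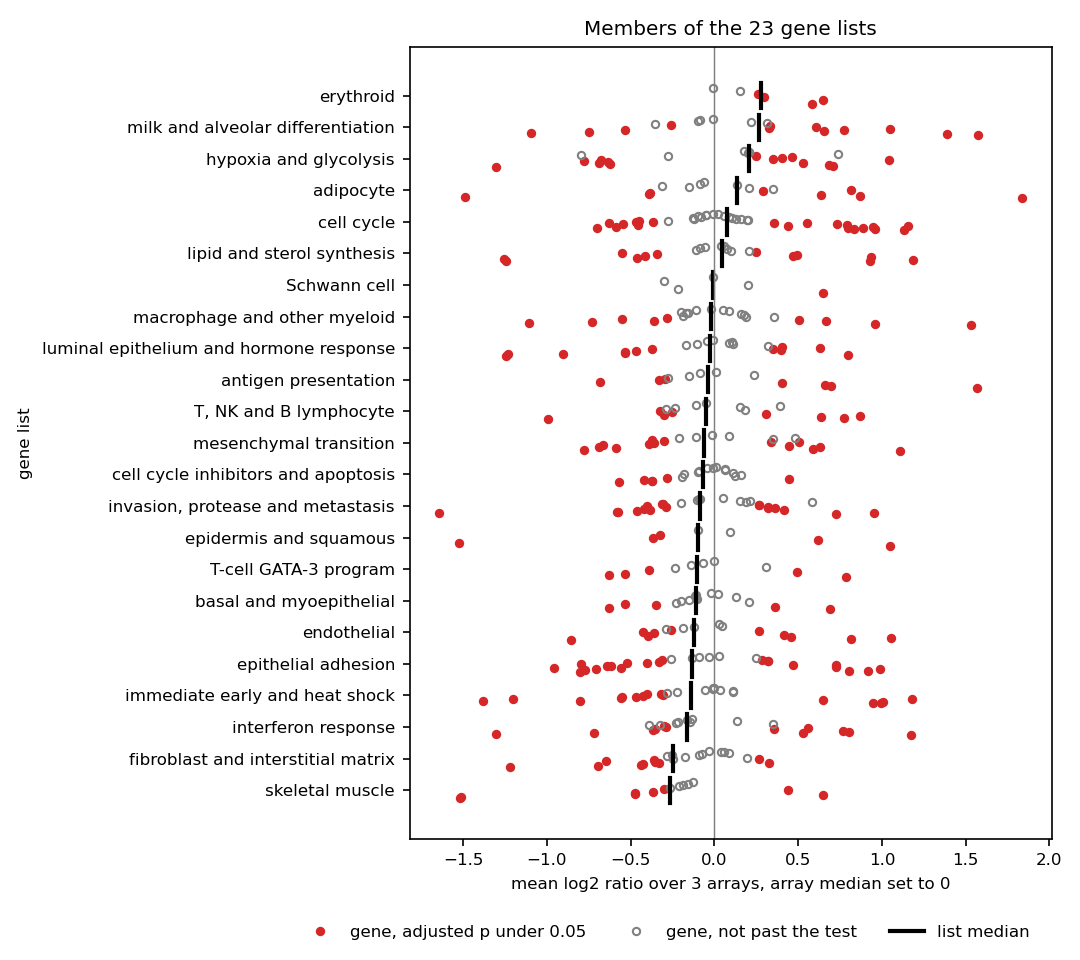
Mean log2 ratio over 3 arrays (x axis, array median set to 0, direction likely) of each measured gene of the 23 lists (y axis); filled points passed the limma test at adjusted p under 0.05, open points did not, and the bar is the list median. Members lie on both sides of 0 in most lists, and the medians run from -0.26 to 0.28.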

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

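The count of 17340 rows stayed within 1.5 times under the values as deposited (18020, of which 51.0% were positive against 56.8%), scaled arrays (18034), a value on at least 2 arrays (17341), a robust eBayes (17186), each probe on its own (22341 of 38975), an adjusted p under 0.10 (20425), the turned sign (17340, with 7499 positive and 9841 negative by construction) and without the 5% of rows of highest SD (17868). It moved to 2289 with an absolute mean of at least 1 and to 4 with the plain one-sample test, which has 2 degrees of freedom per row and borrows no variance across rows. Leaving out 1 array at a time gave 8500 (without array 3) to 19745 (without array 1, which leaves the arrays of 1 title prefix), of which 8448 and 16503 were among the 17340. Alternatives chosen after seeing the data gave 839 of 5138 genes with 2 or more probes and 106 of 1539 with 3 or more, where every probe passed with 1 sign, and 411 rows (3 positive, all unnamed probes, and 408 negative) past the threshold and outside the range of the receptor genes (-1.16 to 1.85). Gata3 kept its sign and call under the deposited, scaled and single-probe values, the missing-value filter, the robust eBayes and each array left out, between 0.74 and 0.83 with adjusted p from 0.00159 to 0.0278. It lost the call in the plain test, an alternative chosen after seeing the data (0.80, adjusted p = 0.0553); the turned sign reverses it by construction. The count of 0 lists called in 1 direction held under every alternative run, fry's directional test included (its test of change in either direction called 23). It also held with members with at least 2 probes (14 lists testable, chosen after seeing the data). A robust eBayes was not run for camera, which has no such option. The power of the estimated-correlation form with 3 arrays was not measured, so its 0 adds little. List medians moved by at least their SD over the arrays in 4 of 23 lists with the values as deposited. They did so in 2, 5 and 3 lists without arrays 1, 2 and 3. Correlations between arrays rose to 0.85, 0.87 and 0.97 for rows of absolute mean at least 0.5. These rows were chosen on the mean of the same arrays, which favours a rise by construction. Of 129 other followed genes past the threshold, 29 lost the call in at least 1 setting, 28 of them without array 3 and Cd74 without array 2 only. By setting, 18 lost it without array 2, 5 without array 1 and 4 with the values as deposited. The other 100 kept it in each setting run for these genes, which did not include the plain one-sample test. That test left 4 of all 31059 rows, so nearly all of the 100 would lose the call in it. Esr1, not called, was the only followed gene to turn sign (-0.0645 without array 1, and 0.235 without array 3). No paired analysis was possible because there was 1 group, with each tumor pair already combined in a ratio.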

Other observations

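All families and tests in this part were chosen after the result they bear on had been seen, except the sign agreement of probe pairs, the reassignment of names for genes with 3 or more probes and the choices of array signs, which were set after the files were seen but before those results.

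Some gene families outside the fixed lists had medians further from 0 than any list, and the proteasome did not. Olfactory receptor genes had a median log2 ratio of 0.62, with 576 of 844 called positive and 45 negative, and vomeronasal receptor genes 0.69, with 89 of 132 positive and 7 negative. Histone genes had a median of -0.90 (6 positive and 40 negative of 60), with H2bc21 lowest at -1.71 and H2bc18 highest. Cytosolic ribosomal protein genes had a median of -0.84 (12 positive and 45 negative of 69), and ran from Rps23 at -1.90 to Rpl39l at 0.94. Keratin-associated protein genes had a median of 0.46 and proteasome subunit genes -0.12. Camera over these 6 families gave adjusted p from 9.0e-14 to 0.00232 for all but the proteasome (adjusted p = 0.0633). With an estimated correlation none passed (camera, adjusted p from 0.325 to 0.415). The unadjusted camera p of the olfactory receptors went from 1.5e-14 to 0.104, so the calls depend on the correlation assumed. The power of the estimated form with 3 arrays was not measured. Neither its lack of calls nor the calls at the preset correlation therefore decide whether these families shifted as sets.

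Some genes had ratios of 1 sign on all of their probes. Among the 1539 genes with 3 or more probes, 106 (47 positive, 59 negative) had every probe past the threshold with 1 sign, where 1000 reassignments of gene names gave a median of 66 (45 to 90), so most of the 106 are expected by chance. For 2 or more probes the count was 839 of 5138, against a median of 720 (642 to 794). The largest of the 106 were Ap1s3, an adaptor complex subunit, at 1.40 (3 probes, the lowest at 1.35), the chaperone gene Hspa8 at -1.38 (-1.61 to -1.04), the proteasome gene Psma3 at 1.20 (1.08 to 1.29), Spata2 at 1.17 (0.87 to 1.51), Vps37a, an ESCRT component, at 1.13 (4 probes, 0.84 to 1.35), and alpha-actinin 4 (Actn4) at -1.07 (4 probes, -1.27 to -0.68).

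Of all rows, 55.8% passed the threshold (17340 of 31059). Expression differences of whole genes as the main cause are argued against by probe pairs: only 56.1% of the 1307 called pairs had 1 sign, under the 75% set before that share was seen, although probes for different splice forms could oppose each other, and 13 of 19 genes with 10 or more probes had at least 75% of them with 1 sign. An effect of the single probe, repeated on every array, is a candidate explanation, since r between the probes of a gene was 0.105 while r between arrays was at least 0.770. Differences in a part of the genes stay open, because 106 genes with 3 or more probes agreed throughout against at most 90 in 1000 reassignments of gene names, an excess that a base composition shared by a gene's probes could also give. The 3 arrays allow only 4 choices of sign, of which 1 (the real one) reached 17340 rows and the highest other reached 0, too few choices for a share under 0.05.

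Probes of receptor genes known from sensory neurons lay above the median of all rows, with a median of 0.64. A single shift of all gene names against the probe rows is argued against by the 839 genes whose 2 or more probes all passed with 1 sign. With all names moved together by up to 500 rows of the file either way, the count was at most 763. With names reassigned at random it was at most 794. Wrong names in only a part of the rows were not tested and stay open. Base composition of the probes acting on the dyes may be a source. The receptors and the keratin-associated protein genes (0.46) lay on one side. The histone genes, at -0.90, and the ribosomal protein genes, at -0.84, lay on the other. Probe sequences were not used here and the 2 dyes were never swapped, so this cannot be told apart from expression. Brightness of the probes is unknown, so an effect of it on the ratios was not tested and stays open too.

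Arrays 2 and 3 were closer to each other (r = 0.946) than either was to array 1 (at most 0.781). A difference between array series, marked by the title prefix, may be the source, but only 1 array has the other prefix, so the series and the tumor on it cannot be told apart.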
